A study of Saccharomyces cerevisiae with 116 samples.

How the data were processed

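RNA was measured in diploid budding yeast (Saccharomyces cerevisiae) from a pair of mutation accumulation experiments. In mutation accumulation, lines descended from 1 ancestor are carried through repeated bottlenecks of a single cell, so that most new mutations and chromosome gains or losses are kept whatever their effect on growth. Per the labels, the experiment named HH here started from a homozygous ancestor of S288C descent with ade2, lys2, his3, leu2 and ura3 alleles and ran for 2063 generations. The experiment named Hh started from a heterozygous ancestor of oak isolate and DBVPG1106 descent with a ura3 allele and ran for 2108 generations. Per the labels' protocols, 3 colonies of each line were grown to log phase in rich glucose medium at 30 °C, and stranded libraries were read as single ends of 75 bases. The libraries were grouped by the labels into 10 aneuploid and 11 euploid HH lines, 10 aneuploid and 5 euploid Hh lines, the HH ancestor in 2 runs and the Hh ancestor. The series text states 12 euploid HH and 6 euploid Hh lines. No library was left out of the grouping, and the reason for the difference is not known. The titles place 3 libraries in the euploid line HH2, while the descriptions of its replicates 2 and 3 name other lines. The titles were used. The karyotype of each aneuploid line was also taken from the labels and never from the values.

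The deposited count files hold whole-number counts of reads per gene, made by the authors with HTSeq 0.6.1pl after Trim Galore 0.4.4 and TopHat2 2.1.1 on the build sacCer3, per the submitters' processing notes, which also name FastQC 1.8.0, SAMtools 1.3.1 and DESeq2. The deposited FPKM table holds length- and depth-normalised fragment values for the same libraries, and the notes name Cufflinks, Cuffnorm and Cuffdiff 2.2.1. Which of these steps used which settings is not given in the sources used here. The strand setting of the counting is not given either, so overlapping genes on opposite strands are uncertain. Counts of reads that fell in no gene, or that did not align uniquely, were left out of library sizes and tests. Reads that did not align uniquely made up 7.1% to 68.4% of a library, with a median of 19.2% in the HH libraries named SC, 28.4% in the HH libraries named X and 9.8% in the Hh libraries. Reads of near-identical genes can be lost in this way, and values of such genes are uncertain. Of 7126 features in the count files, 6086 matched the R64 reference annotation, 6048 by locus tag, 31 by symbol and 7 by synonym. The count files carry no coordinates, so positions are those of R64, and chromosome membership was used only for matched genes. For 104 of the 116 libraries the count file correlated best with its own FPKM column. For the other 12 another column correlated better, in 11 of them one of the same line or ancestor run. Replicates 1 and 3 of HH1 each matched the column of the other (r with their own of 0.196 and 0.274), so the replicate order may differ between the files there. In the HH ancestor, replicates 2 and 3 of run 1 and replicates 1 and 2 of run 2 did so too. The 3 libraries of the Hh ancestor each matched another of the 3. Their r with their own column was 0.763 to 0.917, so the order is in doubt there as well. Settings by replicate number took the count files as labelled. The libraries labelled HH123, Hh59 and Hh11 replicate 1 matched their own columns. No pair of colonies of a line agreed within sampling noise, the lowest chi-square per degree of freedom being 7.04 over genes with at least 50 counts in the pair, so each library was counted as its own sample. Libraries held 4129372 to 12148296 reads in genes.

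Colonies of a line share its mutations and karyotype, so counts of the 3 colonies were summed and the line was the replicate. The p-values of the class comparisons measure the spread between lines, and those of lines and ancestors measure the spread between colonies. Aneuploid and euploid lines were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust dispersion, TMM scaling, filterByExpr), with a term for the name series in HH, on the assumption that SC and X in the names of line libraries stand for the 2 runs named for the HH ancestor. The labels do not state this link for the lines. Run 1 of the HH ancestor carries SC in its names, while run 2 and the Hh ancestor carry other names and were placed with X on the same assumption. Benjamini-Hochberg adjustment was used throughout, with a threshold of 0.05. The difference of the class effects between experiments was tested as an interaction in 1 fit. Each line was also compared with the ancestor of its own experiment and name series in a fit on single libraries, leaving out genes on the line's labelled chromosomes, and the class medians of the counts of calls were compared by exact permutation. The ancestors were compared in 1 fit of their 8 libraries.

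For chromosome dosage, log2 of CPM (counts scaled to library size) plus 0.5 was set against the mean over euploid lines and ancestor of the same experiment and name series, over genes with a reference mean of at least 10 CPM. Each library was centred on genes of its own disomic chromosomes, and the median over the genes of a chromosome was averaged over the 3 colonies. The events were tested against 0 and against log2(3/2) with two-sided exact sign-flip tests. Gene by gene, the slope of log expression on log copies was tested against 1 (proportional dosage) and against 0 with edgeR. Chromosome X of Hh was left out there because its label is partial.

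The 21 gene lists tested were ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, general stress, heat shock chaperones, proteasome, unfolded protein response, oxidative stress, glycolysis and ethanol formation, citric acid cycle, respiratory chain and ATP synthase, amino acid biosynthesis, purine biosynthesis, methionine and sulfate assimilation, phosphate regulon, iron regulon, ergosterol biosynthesis, cell wall, DNA damage and replication stress, haploid mating genes, and meiosis and sporulation. The last pair marks other cell states that a diploid culture could hold. Camera of limma 3.58.1 was run with a preset correlation of 0.01, and again with an estimated correlation, and fry was run beside it. A list of auxotrophy markers served only as a label check. The genes named are, among those past the threshold with an average log2 CPM of at least 4, the 10 largest rises and 10 largest falls, or the 10 smallest p-values where fewer than 10 passed. In addition up to 4 members with the smallest p are named per list, the 10 largest departures from proportional dosage, and the 5 largest rises and falls between the runs of the HH ancestor. The grouping, tests, lists, naming rule and the alternatives not said otherwise were fixed before the data were examined.

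Alternatives were DESeq2 1.42.0, RLE size factors, TMM factors from chromosomes that no line gained or lost, other count filters, a copy number offset, limma-voom on single libraries with the correlation within lines, a block on replicate number, other references, FPKM (log2 of FPKM plus 1) in place of counts, single name series, and leaving out each replicate number or each Hh euploid line. Leaving out libraries or lines that go against their karyotype label, or that stand apart, was chosen after seeing the data. Leaving out each Hh euploid line was fixed beforehand for the count of genes, and chosen after seeing the data for the gene lists and the calls per line, as was leaving out every other line in turn. Tables and permutations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.

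Every step across genes was tested on simulated data drawn from the means and library sizes of these samples. With 200 changed genes, the class fit recovered 56.7% of changes of 1.5-fold, 90.3% of 2-fold and 100% of 4-fold changes in HH, and 41.3%, 90% and 100% in Hh. Among unchanged genes it made 8 false calls in HH and 10 in Hh, against 17 and 22 for DESeq2, 46 and 60 for limma-voom on single libraries and 43 and 56 for limma-voom with the block. The fit of lines against their ancestor recovered 51.5% of mixed changes in HH and 49.5% in Hh, the ancestor fit 59.5% and the interaction 57.5%, with 0, 0, 0 and 5 false calls. Of genes held flat on altered chromosomes, the test of the slope against 1 recovered 10% in HH and 0% in Hh, so a low count of departures carries little information about single genes. The median coefficient of biological variation was 0.227 between HH lines and 0.218 between Hh lines, on counts summed over colonies. Between colonies, in the fits on single libraries, it was 0.258 in HH and 0.238 in Hh. In the fit of the ancestors alone it was 0.173 between colonies. A sum over colonies varies less than a single library, so the values of lines and of colonies are not on one scale. Whether lines differed by more than colonies of a line was not tested.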

Results

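Gene expression was measured by RNA sequencing in 116 libraries of diploid yeast mutation accumulation lines and their ancestors, to compare lines that had gained or lost chromosomes with lines that had kept 2 copies of each. The HH experiment contributed 10 aneuploid and 11 euploid lines and the Hh experiment 10 aneuploid and 5 euploid lines, each with 3 colonies. The HH ancestor was read in 3 libraries in run 1 and in 2 libraries in run 2, and the Hh ancestor in 3 libraries. The HH libraries named SC held 4129372 to 9938460 reads in genes, the HH libraries named X 5062829 to 11368002 and the Hh libraries 4675391 to 12148296.

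Marker genes were read first as a check of the strain labels. HIS3, which encodes an enzyme of histidine synthesis, had no read in the ancestor libraries of HH and 180 ± 25.3 CPM (SD, n = 3) in the Hh ancestor, at least 929-fold higher against a floor of 3 counts over the HH run 2 group. URA3, an enzyme of uracil synthesis, had no read in the Hh ancestor and 60.1 ± 28.2 CPM (SD, n = 2) in HH run 2, at least 562-fold higher against the same kind of floor. These floors cover counting error only. In the Hh lines URA3 reached at most 2 counts in a library, while in the HH lines HIS3 had 26 reads in HH112 replicate 1, 18 in HH123 replicate 1, 11 in HH29 replicate 2 and 4 in HH29 replicate 1. The absence of HIS3 from the HH ancestors and of URA3 from the Hh ancestor followed the alleles their labels name. URA3, however, is also among the alleles the HH label names and was read in both HH runs (30.4 CPM in run 1). ADE2, LYS2 and LEU2, the genes of adenine, lysine and leucine synthesis whose alleles the HH label names, were read in both strains, with 195, 151 and 741 CPM in HH run 2 and 110, 253 and 60.4 in the Hh ancestor, so the levels of these 4 genes do not check the HH label.

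Whether transcript levels followed chromosome copy number was asked first for whole chromosomes. Chromosomes labelled trisomic were expressed at a median log2 ratio of 0.48 ± 0.19 (SD, n = 10 events) in HH and 0.50 ± 0.08 (SD, n = 10 events) in Hh, where 3 copies in proportion would give 0.585. The level was 0.56 for chromosome XIV in HH9, 0.60 for VIII in HH108, 0.57 for XVI in HH112, 0.54 for V in Hh4, 0.57 for VII in Hh61 and 0.61 for IX in Hh76. Monosomic chromosome IX was at −0.97 ± 0.00 (SD, n = 3 colonies) in HH29 and at −0.93 ± 0.02 (SD, n = 3) in HH108, and tetrasomic chromosome XVI of Hh8 at 0.95 ± 0.04 (SD, n = 3), where proportion gives −1 and 1. The trisomic levels differed from 0 (two-sided exact sign-flip p = 0.00391 in HH, 0.00195 in Hh) and lay below 0.585 (exact p = 0.00586 in each). Of 72 labelled pairs of a library and a chromosome, 7 lay nearer to 2 copies than to the label. These were chromosome V of the library labelled HH123 replicate 1 (−0.01), VII of the 3 libraries labelled HH152 (−0.07, −0.03 and 0.05), I and XV of the library labelled Hh11 replicate 1 (0.39 and −0.01) and VII of the library labelled Hh59 replicate 1 (0.01). Without them the trisomic mean was 0.56 in HH (n = 9, exact p = 0.0117 against 0.585) and 0.54 in Hh (n = 10, exact p = 0.00977), and the mean of the 3 monosomic events moved from −0.82 to −0.98. In HH the test against 0.585 no longer passed, at a similar level, with total-count scaling without centring (0.48, exact p = 0.0977) and with genes of at least 50 CPM (0.49, exact p = 0.0938), while total-count scaling took the Hh mean to 0.30.

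**Figure D1:**
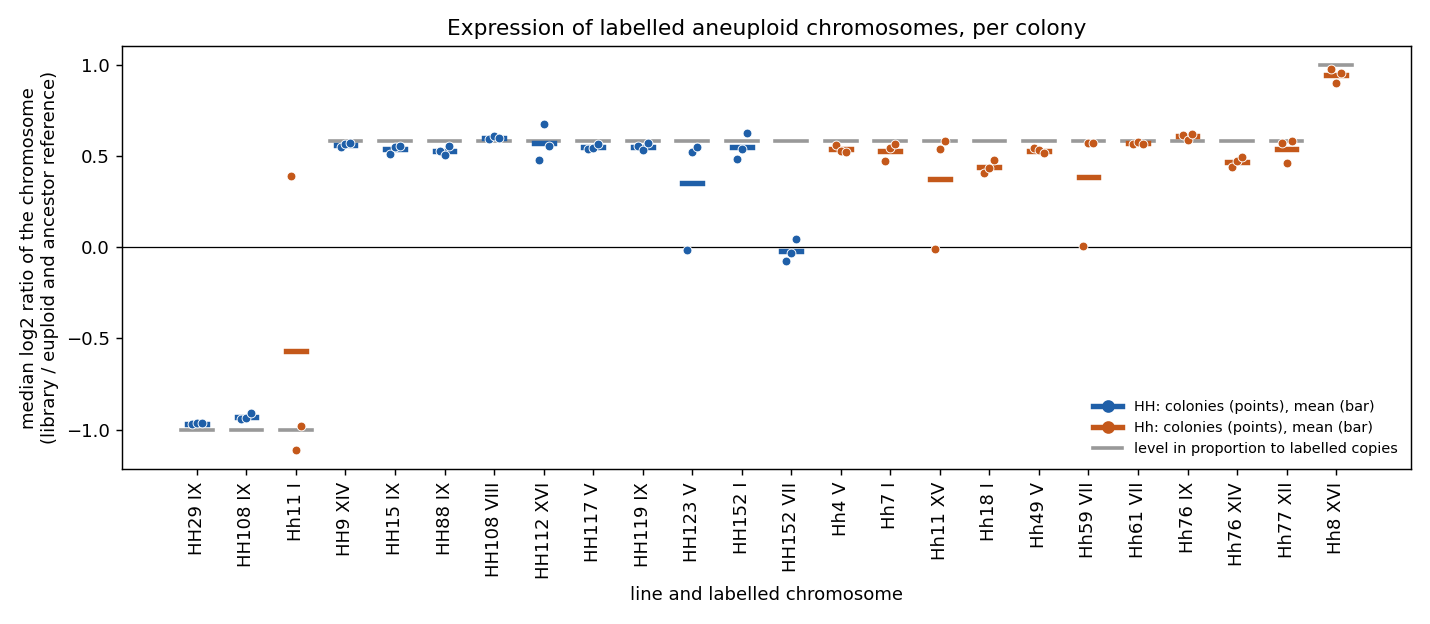
The vertical axis gives the median log2 ratio of each labelled aneuploid chromosome for every colony (points), with the mean of 3 colonies (coloured bars) and the level in proportion to the labelled copies (grey bars), for HH lines in blue and Hh lines in orange. Most trisomic events sit between 0.44 and 0.61, the 3 colonies of HH152 lie near 0 on chromosome VII, and 1 colony each of HH123, Hh11 and Hh59 lies apart from the others of its line.

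Some chromosomes departed from 2 copies without a label. Chromosome VIII was raised in the 3 libraries labelled HH152 (0.53, 0.55 and 0.59) and chromosome XII in the 3 libraries labelled Hh18 (0.51, 0.50 and 0.55) and in the library labelled Hh11 replicate 1 (0.52). Euploid and ancestor libraries spanned −0.24 to 0.21 over 896 chromosome medians (SD 0.0416). Chromosome X of Hh76, labelled as a partial gain, was at 0.25 as a whole. Divided into 8 parts of about equal gene number, the first 4 parts were at 0.53, 0.57, 0.50 and 0.51 and the last 4 at 0.06, −0.05, 0.02 and 0.10. The 4 raised parts held genes starting at positions 466 to 387657 of R64 and the others genes starting at 388385 to 742848, and where within the neighbouring parts the level changed was not resolved.

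**Figure D2:**
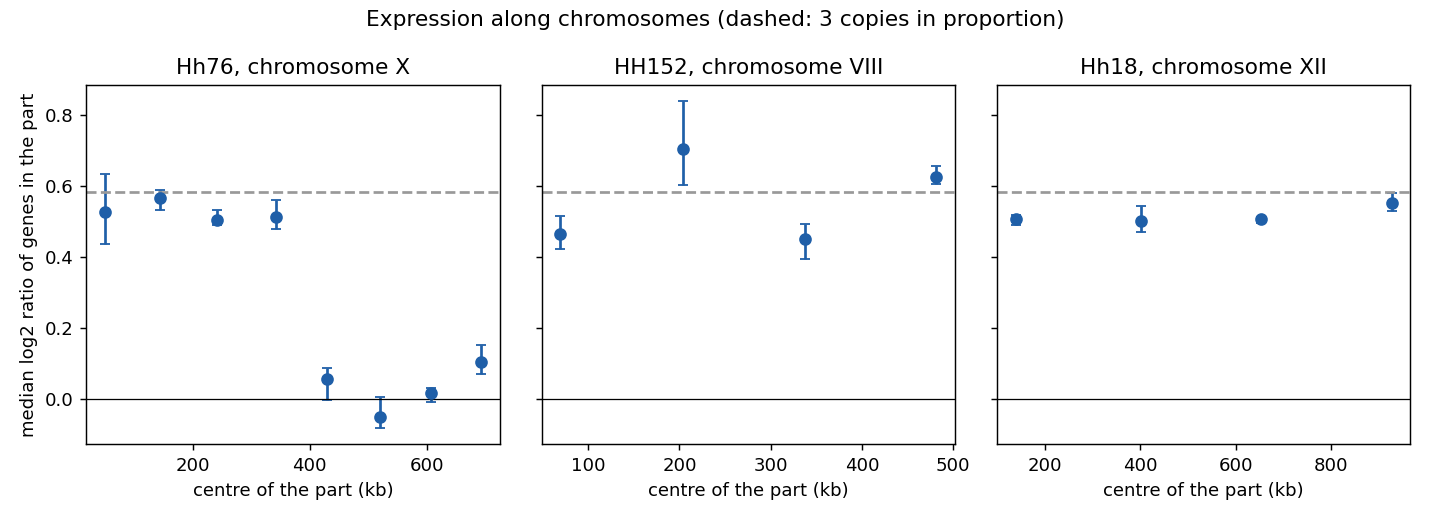
Each panel gives the median log2 ratio of genes against the position of their part along the chromosome in kilobases, for chromosome X of Hh76, VIII of HH152 and XII of Hh18, with points for the mean of 3 colonies and bars from the lowest to the highest colony. Chromosome X of Hh76 falls from 0.51 to 0.06 along its length, while the 4 parts of HH152 VIII and of Hh18 XII stay above 0.45.

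Single genes were tested for departure from proportional dosage, in which the slope of log expression on log copies is 1. The median slope was 0.732 over 2220 genes in HH and 0.799 over 2952 genes in Hh. Without the doubted libraries and lines it was 0.859 and 0.894, and the value of 0.732 includes chromosome VII of HH at −0.02. On simulated data the median error of the slope was −0.0758 in HH and −0.044 in Hh for genes in proportion. For genes held flat it was −0.0776 and −0.0826. Part of the shortfall below 1 may thus come from the method, and counts below and above 1 may lean the same way. On chromosome VIII of HH108, IMD2, an inosine monophosphate dehydrogenase of guanine nucleotide synthesis, had a slope of 6.89 ± 1.15 (SE, adjusted p = 0.00523), and BAT1, the mitochondrial branched-chain aminotransferase, 6.08 ± 0.84 (SE, adjusted p = 0.0021). YHR033W and QCR10, a subunit of the cytochrome bc1 complex, had slopes of −3.35 and −3.00 on the same chromosome. These fits took copies from the labels, so HH152, raised on VIII without a label, counted as 2 copies there. The other genes named by the rule lie on chromosome VII, which was at 2 copies by expression in the line labelled HH152. They were MPC3, a mitochondrial pyruvate carrier subunit (−5.60), MAL12, a maltase (−4.69), MAL11, a maltose transporter (−3.19), YGR174W-A (−3.16), the zinc transporter ZRT1 (−3.11) and COX13, a subunit of cytochrome c oxidase (−3.03). In HH, 182 genes departed, 159 below and 23 above a slope of 1, of which 117 lie on VII and 45 on VIII, and 621 differed from a slope of 0. Without the doubted libraries and line, 74 of 1612 departed, 36 below and 38 above, 55 of them on VIII, where HH108 is the only altered line. With all libraries, chromosome IX, which rests on 5 lines, had 12 below and 1 above. Chromosome VIII had 25 below and 20 above, so the even split rests largely on VIII. In Hh the edgeR test called 1 gene, YPL257W on chromosome XVI (slope −1.94 ± 0.48, SE, adjusted p = 0.0329), with 317 genes at an unadjusted p under 0.05 and 52 called by DESeq2, while 1080 differed from a slope of 0. Without the doubted libraries 13 departed, and without Hh18 as well 11. Others with the smallest p in Hh did not pass: YOR186W (5.31), FUN14 (0.14), SEO1 (−0.21), PHO81, a regulator of the phosphate pathway (2.30), YOR062C (3.84), MSB1 (−1.07), PHO11, an acid phosphatase (0.07), FSF1 (−0.85) and the aldehyde dehydrogenase ALD6 (−1.34), with adjusted p of 0.0688 to 0.113. FUN14, SEO1 and PHO11 lie on chromosome I and YOR186W, YOR062C, MSB1 and FSF1 on XV. The labelled copies of both in Hh11 include the doubted replicate 1. Without the doubted libraries and Hh18 the median slope went from 0.59 to 1.01 on I and from 0.64 to 0.91 on XV. On XII, where Hh18 was raised without a label and counted as 2 copies, it went from 0.79 to 0.90. Slopes of most chromosomes rest on 1 aneuploid line, so a departure on these cannot be told apart from another mutation of that line.

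Aneuploid HH lines were then compared with euploid HH lines over all chromosomes. IMD2 had the smallest p, at 223 ± 266 CPM (SD, n = 10) in aneuploid and 42.0 ± 24.8 (SD, n = 11) in euploid lines, a log2 difference of 2.29 ± 0.49 (SE). BAT1 was at 1.51 ± 0.44 (SE), YOL014W at 1.34, the mitochondrial aldehyde dehydrogenase ALD5 at 1.04, the cysteinyl-tRNA synthetase CRS1 at 0.69, IRC22 at 0.36 and GTT3 at 0.35. LDS1, a protein of spore lipid droplets, was at −0.99, MIN3 at −0.76 and PET111, a translational activator of a mitochondrial gene, at −0.43. None of these passed (adjusted p = 0.502 for each). The edgeR test called 0 of 6130 genes, with 601 at an unadjusted p under 0.05 where 306.5 would arise by chance. DESeq2 called 1, IMD2 (adjusted p = 0.042, against up to 0.960 under the other alternatives), and limma-voom 0. IMD2 was at 1.24 without HH108. Within the SC lines alone and within the X lines alone the count was 0 as well.

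Among the gene lists in HH, the respiratory chain and ATP synthase genes were lower in aneuploid lines in 32 of 32 members (median −0.36) and mitochondrial ribosomal proteins in 59 of 67 (−0.14). The general stress list was lower in 37 of 49 (−0.20), the citric acid cycle in 13 of 14 (−0.09) and haploid mating genes in 18 of 20 (−0.12). On that last list the euploid line HH1 stood apart, with a mean level of 1.295 relative to the mean over HH lines, where the next line was at 0.30. Higher in aneuploid lines were ribosomal proteins in 130 of 136 members (0.32), ribosome biogenesis in 108 of 115 (0.21), glycolysis and ethanol formation in 16 of 17 (0.36), amino acid biosynthesis in 32 of 39 (0.30), purine biosynthesis in 10 of 10 (0.57), methionine and sulfate assimilation in 21 of 23 (0.42) and ergosterol biosynthesis in 22 of 23 (0.25). No member passed, over all genes or adjusted over the list alone. Camera called these 12 lists, with adjusted p from 7.63e-14 for the respiratory chain to 0.0243 for haploid mating genes. The adjusted p = 0.608 with an estimated correlation for 11 of them and 0.655 for methionine and sulfate assimilation, and fry called 0, with adjusted p of at least 0.488. By exact permutation over lines, chosen after seeing the data, 0 of the 21 lists passed in HH. On the respiratory chain aneuploid lines spanned −1.96 to 0.63 and euploid lines −0.46 to 0.79 (exact permutation p = 0.0747, adjusted 0.492). Some aneuploid lines thus lay at the euploid level, without allowance for the name series. These levels per line, and those of ribosomal proteins below, were not adjusted for it. Aneuploid and euploid lines gave 15 and 27 SC libraries but 15 and 6 X libraries. On the respiratory chain the class means were −0.42 and 0.38, while the permuted difference, taken within series, was −0.51. Single directions and calls rested on HH108, whose libraries held more reads that did not align uniquely (30.4% to 37.8%) than other SC libraries (median 19.2% over all of them): without it purine biosynthesis and methionine and sulfate assimilation turned lower (camera adjusted p = 0.552 and 0.357), the citric acid cycle and amino acid biosynthesis were no longer called (0.357 and 0.0526), and the proteasome (2.13e-07, lower) and the cell wall (0.034, higher) were. Without the name series term haploid mating genes were no longer called (0.130), the unfolded protein response was (0.0106, higher), and heat shock chaperones turned lower and were called (0.0279). Without the doubted libraries and line heat shock chaperones (0.0195, higher) and the proteasome (0.043, lower) were called, as was the unfolded protein response with a copy number offset (0.026, higher). Lines other than HH108, left out in turn after seeing the data, ended the call of haploid mating genes for HH9, HH29, HH115 and HH119 (0.0528 to 0.0915), of methionine and sulfate assimilation for HH29 (0.0619) and of the citric acid cycle for HH50 (0.0575). Without HH1 haploid mating genes were still called (0.0441). Ribosomal proteins, where HH4 was lowest at −1.28, and 6 other lists were called whichever of the 21 lines was left out. Aneuploid lines spanned −0.40 to 1.14 on ribosomal proteins and euploid lines −1.28 to 0.29, so the classes overlapped (exact permutation p = 0.34, adjusted 0.595). Of lists not called with all lines, heat shock chaperones were called without 10 of the 21 lines in turn, the proteasome and the unfolded protein response without 6 each, the cell wall without 4 and oxidative stress without HH88 (0.028). In the fit of all lines the remaining lists were not called and had medians of 0.21 for heat shock chaperones (16 of 22 higher), −0.06 for the proteasome (23 of 34 lower), 0.15 for the unfolded protein response (12 of 14 higher), 0.16 for oxidative stress (16 of 20 higher), 0.07 for the phosphate regulon (13 of 15 higher), 0.09 for the iron regulon (12 of 17 higher), 0.14 for the cell wall (13 of 19 higher), −0.01 for DNA damage and replication stress (6 of 11 lower) and −0.03 for meiosis and sporulation (11 of 17 lower). The DNA damage median turned to the other sign, at 0.0002, with TMM factors from unaltered chromosomes.

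In Hh, aneuploid lines had lower transcript levels of methionine metabolism and uptake than euploid lines. Rises and falls here are of aneuploid against euploid lines. The ancestor is not part of this comparison, so which class departed from it was not tested for these genes. SAM1 and SAM2, near-identical S-adenosylmethionine synthetases whose reads may be split or lost between them, changed by −1.89 ± 0.27 and −1.46 ± 0.21 on the log2 scale (SE, adjusted p = 0.00187 for each). MUP1 and MUP3, methionine permeases, changed by −1.70 ± 0.28 (adjusted p = 0.00608) and −1.84 ± 0.19 (adjusted p = 0.00011), MUP3 from 116 ± 34.4 CPM (SD, n = 5) in euploid to 29.0 ± 8.27 (SD, n = 10) in aneuploid lines. BNA3, a kynurenine aminotransferase, fell by 1.47 ± 0.18 (adjusted p = 0.000382). The largest falls also held FRE7, a metal reductase (−1.92), CYC7, an isoform of cytochrome c (−1.59), and YNR014W (−1.89), YLR177W (−1.49) and YKL068W-A (−1.43), with adjusted p of 0.0168 to 0.0393. The largest rises in aneuploid lines included the peroxisomal acyl-CoA synthetase FAA2 (2.13 ± 0.49), the acyl-CoA oxidase POX1 (1.77 ± 0.42), the multifunctional enzyme FOX2 (1.81 ± 0.46), the isomerase-like DCI1 (1.71), the isocitrate dehydrogenase IDP3 (1.69) and FAT3, linked to fatty acid uptake (1.96), with adjusted p of 0.0228 to 0.0318. FDH1, formate dehydrogenase, rose by 2.63 and YPL276W, which resembles it in sequence so that both values are uncertain, by 2.42, ADH2, the glucose-repressed alcohol dehydrogenase, by 2.04 and the cell wall protein TIP1 by 1.99, with adjusted p of 0.0388 to 0.0443.

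The edgeR test called 611 of 6189 genes in Hh, 261 higher and 350 lower in aneuploid lines, with 1927 at an unadjusted p under 0.05. On chromosomes that no Hh line had gained or lost, 278 of 2462 genes passed, and on altered ones 293 of 3302. With TMM factors from unaltered chromosomes 341 were higher and 274 lower, and with DESeq2 1109 passed. The count varied with the lines included: it was 26 without Hh5, 27 without Hh3 and 37 without Hh2, against 859 without Hh1 and 639 without Hh9. Without both Hh5 and the aneuploid line Hh8, a choice made after seeing the data, it was 849, with 366 higher and 483 lower and 518 shared with the 611. Leaving out 1 aneuploid line, likewise chosen after seeing the data, gave 1547 without Hh8 (610 of them among the 611), 223 without Hh7, 249 without Hh49, 306 without Hh59, 331 without Hh76, 402 without Hh61 and 476 to 618 without 1 of the others. It was 177 without the single doubted libraries and 53 without these and Hh18. Of the 57 genes named here or under the lists that passed, 9 passed under each of 19 alternatives, namely SAM1, SAM2, MUP1, MUP3, BNA3, MET2, MET5, GSH1 and HSP42. Leaving out 1 aneuploid line at a time was not among these 19.

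Of the gene lists in Hh, methionine and sulfate assimilation had a median of −0.97, with 21 of 23 members lower, 15 passed and 18 passed adjusted over the list alone. MET5, a subunit of sulfite reductase, fell by 1.11 and MET2, homoserine acetyltransferase, fell by 1.36. Camera gave an adjusted p = 1.88e-17, the adjusted p = 0.0237 with an estimated correlation, and fry gave 8.96e-05. As the mean level of the list per line, relative to the mean over Hh lines, aneuploid lines were at −0.28 ± 0.16 (SD, n = 10) and euploid lines at 0.56 ± 0.27 (SD, n = 5). The highest aneuploid line, Hh11, at 0.03 lay under the lowest euploid line, Hh9, at 0.15, but without the single doubted libraries the classes overlapped, with the highest aneuploid line at 0.18 and the lowest euploid line at 0.13. An exact two-sided permutation over lines, chosen after seeing the data, gave p = 0.000333, the smallest possible with 3003 splits, and 0.00699 adjusted over the 21 lists. Without the doubted libraries it gave an exact p = 0.000666, adjusted 0.014. Heat shock chaperones had a median of −0.46 with 19 of 22 lower, 11 passed and 12 passed adjusted over the list alone. The small heat shock protein HSP42 (−1.34), the disaggregase HSP104 (−1.13) and the co-chaperones SIS1 (−1.05) and MDJ1 (−0.88) fell. Camera gave an adjusted p = 2.72e-06 and fry 0.035, with adjusted p = 0.608 with an estimated correlation and 0.0443 by exact permutation over lines.

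**Figure D3:**
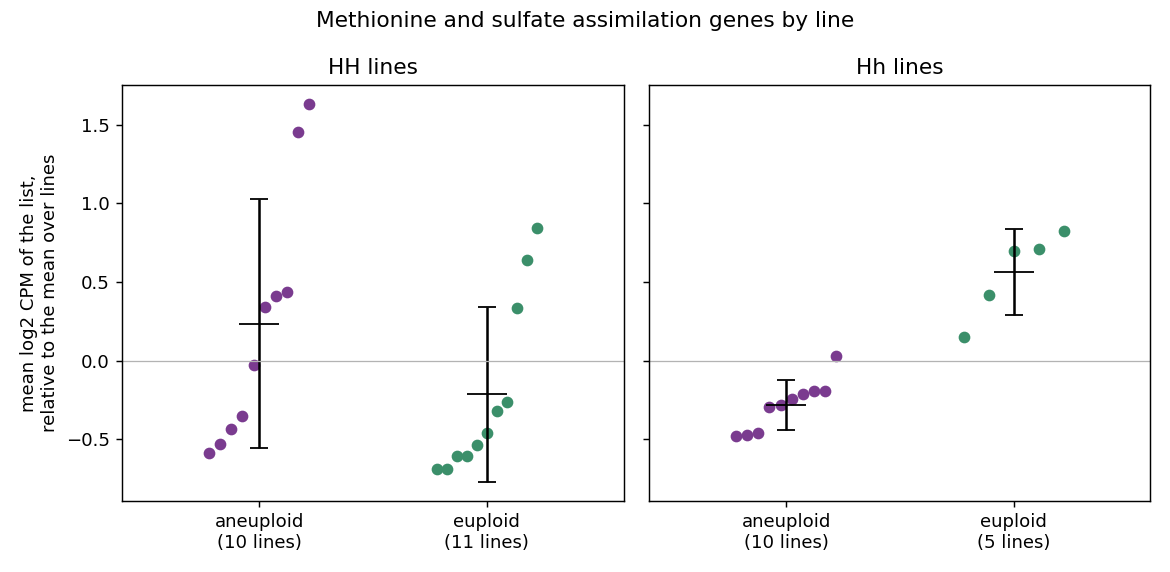
The vertical axis gives the mean log2 CPM of the methionine and sulfate assimilation genes per line, relative to the mean over lines of the experiment, for aneuploid and euploid lines of HH (left) and Hh (right), with the mean and SD. In Hh the 10 aneuploid lines sit at or below 0.03 and the 5 euploid lines at or above 0.15, a separation that is lost without the library labelled Hh11 replicate 1 and that of Hh59 replicate 1 (0.18 and 0.13), and the classes overlap in HH.

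Mitochondrial ribosomal proteins were lower in 66 of 67 members in Hh (median −0.54), with 15 passed, 45 passed adjusted over the list alone, among them MRPL37 (−0.91), MRPL33 (−0.66), MRPL39 (−0.91) and MRPL20 (−1.07). Glycolysis and ethanol formation had a median of 0.83 with 16 of 17 higher, 13 passed adjusted over the list alone, and 4 passed over all genes, where TPI1 rose by 0.74, GPM1 by 1.22 and TDH3 by 1.21 while the pyruvate decarboxylase PDC5 fell by 1.01. Purine biosynthesis had a median of 0.60 with 9 of 10 higher, 5 passed and 6 passed adjusted over the list alone, including ADE1 (1.02), ADE13 (0.91), ADE17 (1.26) and MTD1 (0.60). The cell wall list had a median of 0.64 (16 of 19 higher, 1 passed, 4 passed adjusted over the list alone), with CWP1 rising by 1.52, and ergosterol biosynthesis 0.28 (16 of 23 higher, 2 passed, 2 passed adjusted over the list alone), with ERG6 and ERG24 rising by 1.05 and 0.53. Ribosomal proteins had a median of 0.35 with 130 of 135 higher and none passed, over all genes or adjusted over the list alone. Camera called these 6 lists with adjusted p of 1.31e-15 to 0.0183. The adjusted p = 0.608 with an estimated correlation for each but ribosomal proteins, where it was 0.835, and fry called none of the 6. Without the doubted libraries and Hh18 ergosterol biosynthesis was no longer called by camera (0.0608), nor was it without Hh77 (0.0566). By exact permutation over lines glycolysis passed (adjusted p = 0.0443), and it did not without the single doubted libraries (0.0629), nor did heat shock chaperones (0.117). On glycolysis euploid lines spanned −1.49, in Hh5, to 0.26 and aneuploid lines −0.34 to 0.82. The permutation was not repeated without Hh5 for this list.

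The other lists were not called in Hh with all lines. Lines were left out after seeing the data. Without Hh5 general stress and the proteasome were called higher (camera adjusted p = 0.0123 for each), without Hh3 the respiratory chain (0.049) and without Hh9 ribosome biogenesis (0.0297). Of aneuploid lines, ribosome biogenesis was called higher without Hh4 (0.0469) or Hh49 (0.0119), the respiratory chain without Hh8 (0.0223) and general stress without Hh18 (0.0367). Without Hh5 and Hh8 general stress (0.021), the proteasome (0.0181), the citric acid cycle (0.0321) and the respiratory chain (0.0117) were called higher, and without the doubted libraries and Hh18 general stress (0.0282) was. General stress had a median of 0.40, with 2 members passed higher, among them the glycogen phosphorylase GPH1 (0.86), and 5 lower, among them TSL1 of trehalose synthesis (−0.63), and 16 passed adjusted over the list alone. Oxidative stress had a median of −0.02, which was 0.01 with TMM factors from unaltered chromosomes, with 4 passed lower and 5 adjusted over the list alone. Those named were GSH1 of glutathione synthesis (−1.04), FLR1 (−0.47), the thioredoxin reductase TRR1 (−0.52) and the peroxiredoxin AHP1 (−1.25). The unfolded protein response was at −0.10 with ERO1 passed (−0.69) and 3 passed adjusted over the list alone, the citric acid cycle at 0.17 with LSC1 (0.63) and LSC2 (0.79) passed and 2 adjusted over the list alone, and the respiratory chain at 0.21 with QCR6 (−0.49) and ATP4 (0.38) passed and 0 adjusted over the list alone. Ribosome biogenesis was at 0.09 with NOC4 passed (0.46), the proteasome at 0.10 with PUP1 (0.47), the phosphate regulon at 0.29 with PHO89 (1.55), DNA damage and replication stress at 0.27 with RAD16 (−0.97) and haploid mating genes at 0.00 with STE4 (0.70). Adjusted over the list alone these had 0, 1, 0, 1 and 1. No member passed, on either adjustment, of amino acid biosynthesis (0.10), meiosis and sporulation (0.16) or the iron regulon, whose median of −0.07 and mean of 0.04 differ in sign.

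The class effect was compared between experiments as Hh minus HH. SAM1 differed by −2.72 (adjusted p = 0.00129), MUP3 by −2.28 (0.0025), MUP1 by −2.51 (0.00597), SAM2 by −2.32 (0.00509) and BNA3 by −2.03 (0.0056), and, among the largest rises in Hh, FAA2 by 2.50 (0.0121), POX1 by 2.50 (0.0387), IDP3 by 2.04 (0.0172) and DCI1 by 2.05 (0.0124). HSP42 differed by −1.35 (0.0079) and IMD2 by −2.22 (0.0371). ADH2 at 2.48 (0.138) and CYC7 at −1.12 (0.255) did not pass. In all 324 of 6357 genes differed, 167 higher and 157 lower, with 1472 at an unadjusted p under 0.05. Within the X name series alone, which holds 5 aneuploid and 2 euploid HH lines, the count was 0. With 2 euploid HH lines this fit has little power, so whether the difference holds within a name series was not settled. The HH class effect in the fit of all lines includes HH108, at a mean level of 1.63 on the methionine list. Aneuploid HH lines averaged 0.24 there, and without HH108 the list turned lower in HH. The interaction was not repeated without HH108, so how far these differences rest on that line was not tested.

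Whether aneuploid lines departed further from their ancestor outside the labelled chromosomes was asked line by line. Chromosomes raised without a label, such as XII of Hh18 and VIII of HH152, stayed in the counts. HH108, trisomic for VIII and monosomic for IX, had 1867 calls off these chromosomes, 866 higher and 1001 lower. Reads that did not align uniquely made up 30.4%, 36.3% and 37.8% of its libraries, against a median of 19.2% in the libraries named SC and 16.8% to 21.0% in the run 1 ancestor it was compared with. Hh8, tetrasomic for XVI, had 517 calls, with 216 higher and 301 lower. Among euploid lines HH4 had 292, HH50 173 and Hh5 1176. These counts moved when 1 replicate number was left out of all lines and the ancestor at once. Run 2 of the HH ancestor, however, has replicates 1 and 2 only. Without replicate 1, 2 or 3 in turn Hh5 had 1, 7 and 879 and Hh8 70, 418 and 119. HH4 had 89, 0 and 266 and HH108 919, 1186 and 1169. HH50 had 1610 without replicate 3, a setting that kept every library of its ancestor, run 2. Without replicate 1 or 2 that ancestor kept 1 library, so the counts of HH50 are not given there. Hh11 rose from 17 to 303 without replicate 1, the doubted library. The median was 3.5 calls in aneuploid and 12 in euploid HH lines (difference −8.5, two-sided exact permutation p = 0.549, n = 10 and 11). It was 4.5 in aneuploid and 1 in euploid Hh lines (difference 3.5, exact permutation p = 0.748, n = 10 and 5). The HH difference was −10.0 within SC lines and −81.5 within X lines (exact permutation p = 1 and 0.286). DESeq2 turned both differences to the other sign, at 34.0 and −131, and so did leaving out replicate 3 (34.5 and −4.0) and, in Hh, replicate 2 (−1.0), again without passing. A block on replicate number turned the Hh difference further than these, with 423 calls in Hh2 and 511 in Hh3, and did not pass either.

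The ancestors were compared for the effect of strain. The largest rises in the Hh ancestor against the HH ancestor of run 2 included ADY2, an acetate transporter (8.96 ± 0.52, SE), ADH2 (7.63 ± 0.44), PCK1, the first committed enzyme of gluconeogenesis (7.63 ± 0.46), ICL1 of the glyoxylate cycle (6.92), the succinate carrier SFC1 (6.92), RGI2 (8.86), FDH1 (8.59), the proline permease PUT4 (8.11) and DPA10 (7.25). FRM2, a nitroreductase-like protein, was lower (−8.87 ± 0.28), as were OYE3, an NADPH oxidoreductase (−7.62), OSI1 (−7.17), the glucose transporter HXT4 (−7.10) and YER188W (−6.50). YBL005W-B and YDR261W-B, transposon genes with near-identical copies elsewhere, were also among the largest falls and are uncertain. The named genes had adjusted p of 9.04e-09 to 0.00187. Of the lists, the respiratory chain had a median of 2.04 with 32 of 32 members passed higher, the citric acid cycle 2.44 with 14 of 14 passed higher, glycolysis −2.86 with 16 of 17 passed lower and methionine and sulfate assimilation −1.77 with 19 of 22 passed lower. Adjusted over the list alone these had 32, 14, 16 and 20. In all 3025 of 6046 genes passed, 1500 higher and 1525 lower. Against run 1 of the HH ancestor 3677 passed, of which 2116 were among the 3025. The same HH ancestor differed between its runs in 3105 genes, 1634 higher and 1471 lower in run 2, so a difference of this size arises between runs without a difference of strain. Whether it came from the cultures, the libraries or the sequencing was not tested. In run 2 FRM2 rose by 7.43, YDR034C-A by 6.36, YBR221W-A by 5.22 and the low-affinity glucose transporters HXT1 and HXT3 by 4.73 and 4.11. SIP18, a protein of desiccation (−5.89), RGI2 (−5.83), YIG1 (−5.73), the high-affinity glucose transporter HXT6 (−5.46) and DPA10 (−5.15) were lower there.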

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

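The tests of chromosomes in 4 parts, of a shared culture of Hh11 and Hh18, of gene correlation within the methionine list and of single euploid lines behind it, and the exchanges of single lines were chosen after the results were seen.

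Among 7 groups tested with Dixon's test for a sample far from the rest, 4 had one. Its critical values assume normal values, while counts of calls lie mostly near 0 with a long tail, so no chance rate is given. HH152 was lowest of the HH trisomic events, with chromosome VII at −0.0209. HH108 with 1867 calls off its labelled chromosomes, Hh8 with 517 and the euploid line Hh5 with 1176 stood apart from the lines of their class. Without replicate 1, 2 or 3 of all lines and the ancestor in turn HH108 had 919, 1186 and 1169, Hh8 70, 418 and 119 and Hh5 1, 7 and 879, and whether colonies of the line or of the ancestor moved these counts was not tested. For these lines, and for HH4 with 292, the real split was 1 of 10 splits of the libraries, too few for a share under 0.05, and the highest of the other splits gave 0 calls for HH108, Hh5 and Hh8 and 7 for HH4. HIS3, with no read in the HH ancestors, had 26 reads in HH112 replicate 1, 18 in HH123 replicate 1, 11 in HH29 replicate 2 and 4 in HH29 replicate 1.

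A single library of HH123, Hh59 and Hh11 went against the karyotype of its line. An exchange of count files after quantification was argued against by the deposited FPKM values, which gave medians of −0.01 (−0.0132) for V of HH123 replicate 1, 0.0081 for VII of Hh59 replicate 1 and −0.0063 for XV of Hh11 replicate 1. The library labelled Hh11 replicate 1 correlated best with Hh18 (r = 0.672, own line −0.21), shared its raised chromosome XII (0.52), and differed from Hh18 replicate 1 by a chi-square per degree of freedom of 3.76, where the next pair of different lines had 8.44 and the lowest pair of colonies 7.04. A wrong label, or a culture or RNA shared with Hh18, may account for it. For HH123 replicate 1 (own line r = 0.330) and Hh59 replicate 1 (−0.0226) a wrong label and the loss of the extra chromosome in that colony cannot be told apart, because undoubted libraries had their own line first in only 27.3% of HH X and 34.8% of Hh libraries.

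Chromosome VIII of HH152 (0.56) and chromosome XII of Hh18 (0.52) were raised without a label, in all 3 colonies of each. A gain of part of the chromosome, or of a few genes, was argued against by the lowest of 4 parts, at 0.45 in HH152 and 0.50 in Hh18. The level is consistent with 3 copies along the chromosome, as a hypothesis, and a karyotype label naming VII in place of VIII for HH152 may be an error, since VII was at −0.02. Whether the gain arose before or after the karyotype was recorded was not tested.

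Aneuploid and euploid lines differed in 611 genes in Hh, and the class effect differed between Hh and HH in 324. Of 100 random splits of the lines, the real one alone gave as many in Hh (1 of 100, highest other 0). The same held for the difference between experiments (1 of 100, highest other 19). All libraries were kept in these splits, which were not repeated without the doubted libraries, where fewer genes passed. Of 50 splits that exchange 1 aneuploid with 1 euploid line, however, 3 gave more than 611, all with Hh8 (1774 for Hh1, 1656 for Hh9 and 814 for Hh2, against 489 for Hh3 and 8 for Hh5), others without Hh8 gave fewer (Hh4 for Hh1 437, Hh4 for Hh9 219, Hh18 for Hh1 208) and 35 gave 0, which points to a structure of the samples that the classes do not describe. For the methionine and sulfate assimilation list, a single euploid line as the cause was argued against by exact permutations of its level without each of them in turn, with an adjusted p of at most 0.042 (differences of −0.74 to −0.95, with or without the doubted libraries), and correlation between its genes by an adjusted p = 0.0237 with an estimated correlation. A shared feature of the 5 euploid lines other than karyotype, such as the day of culture, stays open and was not tested.

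In HH, 0 genes passed by edgeR, with 601 at an unadjusted p under 0.05 and 1 by DESeq2, and 100 of 100 splits gave as many, which a count of 0 makes certain and which decides nothing. The highest of the other splits gave 227, so another division of the lines called more genes than the real one. What lay behind this was not tested. Counts of called lists could not be told from chance division of the lines, since 27 of 100 splits gave at least the 12 lists of HH (highest other 17) and 58 of 100 at least the 8 of Hh (highest other 13).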

How the results depend on the processing

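Settings that leave out doubted libraries or lines, or lines that stand apart, were tests chosen after seeing the data. Where a value changed, the cause was not tested. The 611 genes of the Hh class comparison became 1109 with DESeq2, 918 with a copy number offset, 917 with limma-voom and 1029 with the replicate block (which made 60 and 56 false calls on simulated data), 177 without the single doubted libraries, 53 without these and Hh18, and 26 to 1547 when 1 replicate number or line was left out. The HH class count was 1 with DESeq2 and 0 under its other alternatives. The 324 genes of the difference between experiments became 536 with DESeq2, 0 within the X name series, 137 to 298 without 1 replicate number, 166 without the single doubted libraries and 148 without the doubted lines as well. Called lists fell to 0 with an estimated correlation and 0 with fry in HH, and to 1 and 2 in Hh. With the replicate block the proteasome was called lower in HH (camera adjusted p = 0.0284, against 0.0662).

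Genes departing from proportional dosage numbered 302 with DESeq2 and 74 without the doubted libraries and line in HH. In Hh they numbered 52 with DESeq2, 0 with a minimum of 10 CPM, 7 with the replicate block, 0 to 8 without 1 replicate number, 13 without the single doubted libraries and 11 without Hh18 as well. For YOR062C in Hh, slope minus 1 was −0.51 to 3.54 without 1 replicate number, where the slope itself was 3.84 with all of them. The difference in calls per line turned to 34.0 with DESeq2 in HH and spanned −7.0 to 34.5 without 1 replicate number. In Hh it turned to −131 with DESeq2 and −414.5 with the replicate block (exact permutation p = 0.0769, with 423 calls in Hh2 and 511 in Hh3), and spanned −4.0 to 4.0 when 1 replicate number or euploid line was left out. The HH trisomic mean no longer passed against proportion with total counts without centring and a minimum of 50 CPM, at a similar level (0.48 and 0.49). The tetrasomic level was 0.89 with TMM without centring, 0.99 with a minimum of 50 CPM and 0.90 as a mean over genes.

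Libraries were not treated as paired by replicate number, because not every pair with the same number correlated above 0.1, but in the X series the numbers share some deviation. The mean correlation of deviations was 0.00798 with the same and −0.00426 with another number in HH SC, 0.309 and −0.151 in HH X and 0.182 and −0.0879 in Hh, 32.1%, 77.9% and 56.1% of pairs exceeded 0.1, and 20 of 45, 20 of 23 and 32 of 48 libraries correlated best with their own number. Reads that did not align uniquely were 46.0% in replicate 3 of HH X against 23.8% and 23.7% in replicates 1 and 2, and 17.3% against 8.8% and 9.9% in Hh. Of named genes in the Hh class comparison, 754 of 1083 pairs of a gene and a setting kept direction and call and 329 lost the call. In HH 168 of 169 kept them, but no named gene was called there, so keeping the call meant staying uncalled. In the comparison of ancestors 260 of 260 kept direction and call, and 120 of 120 between runs. Named HH slopes kept theirs in 88 of 94 and lost the call in 6, and named Hh slopes kept theirs in 70 of 98, gained a call in 25, lost it in 2 and turned in 1. Depth limits the low genes most, with 4129372 reads in genes in the smallest library.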

Other observations

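The lines and genes of this part, and the tests of calls against altered genes, were chosen after their values were seen. The 3 libraries of the euploid line HH1 lay above all 65 other HH libraries in 7 of 20 mating genes. The alpha-factor genes MF(ALPHA)1 and MF(ALPHA)2 were at 825 ± 498 and 104 ± 103 CPM (SD, n = 3), against a median of 4.74 and 4.38 in the other libraries, and STE3, the receptor of alpha cells for a-factor, at 79.6 ± 35.6 against 12.96. RME1, a repressor of meiosis, was at 202 ± 12.2 against 9.25, STE18 and STE4, G protein subunits of the pheromone pathway, at 45.6 ± 6.93 and 78.2 ± 26.03 against 2.07 and 28.9, and the kinase FUS3 at 92.6 ± 8.08 against 23.2. The a-factor genes MFA1 (6.80 against 16.99) and MFA2 (3.78 against 4.13) and the alpha-factor receptor STE2 (16.6 against 20.6) lay within the range of the others.

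HH108 had the highest mean level of 21 HH lines, relative to the mean over lines, for purine biosynthesis (1.76), methionine and sulfate assimilation (1.63), glycolysis and ethanol formation (0.88) and oxidative stress (0.83), while the respiratory chain was at −1.50. Against its ancestor NDJ1, a meiotic telomere protein, rose by 6.90, the enolase ENO2 on trisomic chromosome VIII by 4.19 and IMD2 by 4.23, while SIP18 fell by 8.11 (adjusted p of 9.6e-05 to 0.00214, edgeR). SIP18 was also lower in run 2 than in run 1 of the HH ancestor (−5.89), and 30.4% to 37.8% of reads in the HH108 libraries did not align uniquely, against a median of 19.2% in the libraries named SC.

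Among Hh lines the euploid line Hh5 was lowest for glycolysis and ethanol formation (−1.49) and ribosomal proteins (−0.57) and highest for mitochondrial ribosomal proteins (0.98). The copper transporter CTR1 rose by 4.04 against its ancestor and SPS19, a peroxisomal reductase, fell by 5.60. The aneuploid line Hh8 was lowest for amino acid biosynthesis (−0.68), the citric acid cycle (−0.54) and the respiratory chain (−0.48).

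A hypothesis that lines with more genes on altered chromosomes have more calls elsewhere was tested over 10 lines in each experiment. Spearman's rho was −0.152 in HH (two-sided permutation p = 0.668, Pearson r = 0.36, p = 0.189) and 0.112 in Hh (permutation p = 0.758, Pearson r = 0.0358, p = 0.955), with an adjusted p = 0.758 for each rho. Without the 2 lines farthest from the median on the number of genes, r was −0.32 in HH and 0.11 in Hh. The numbers of genes follow the karyotype labels, which the expression of chromosomes went against in HH152 and Hh18. Without HH152 rho was 0.145 (exact permutation p = 0.707, n = 9, r = 0.598, p = 0.0839) in HH, and without Hh18 it was 0.282 (exact permutation p = 0.459, n = 9, r = −0.00712, p = 0.969) in Hh, with an adjusted p = 0.707 for each rho. With 9 or 10 lines a moderate relation is not excluded, so the missed threshold decides nothing. The mean trisomic level differed by −0.02 (−0.0191) between HH and Hh (two-sided permutation p = 0.858), which likewise does not show that the experiments have the same level.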
